A study of Rattus norvegicus with 24 samples.

How the data were processed

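The series measured INO80 occupancy by ChIP-seq in rat nucleus accumbens after cocaine or saline. Chromatin was crosslinked, sonicated and immunoprecipitated with 7.5 µg of INO80 antibody per sample, per the labels' protocols, and input DNA was sequenced beside it. The labels give 24 libraries in 4 groups, with 3 numbered samples per group and 2 runs per sample. Samples were grouped by treatment and by ChIP or input from their titles.

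Peaks were called by the authors with MACS version 2.0.10.20131216, per the file headers, with the 3 ChIP alignments of a treatment given together against its 3 inputs. The headers record a q cutoff of 0.05, an effective genome size of 2e+09, a band width of 150 bp, a tag size of 51 bp and the larger dataset scaled to the smaller. They also record 1 tag kept per position, a fragment length of 54 bp for cocaine and 52 bp for saline, and local backgrounds taken over 1000 and 10000 bp. Alignment names in the headers state merged lanes, unique reads and removed duplicates. The genome build is rn6, per the submitters' processing notes, and the aligner is not given in the sources used here. Removing duplicates caps the pileup at 108 for cocaine and 104 for saline, and 25 peaks of each list lay at that ceiling. This flattens any region full of reads, ChIP and input alike.

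The deposited pileup is a signal, the number of ChIP fragments stacked at the summit, not scaled here. The fold is a ratio made by the authors' caller, pileup plus 1 over local input background plus 1. The p-value is deposited as a −log10 value from a Poisson test of the pileup against the local background, and the q-value column was not used here. Both relations were checked in the values, and recomputed −log10 p differed from the deposited ones by less than 0.0001. Peak length and summit position are given per the file headers in bp. Depth per pool after filtering was 43489910 and 37905014 ChIP tags and 101490635 and 100697179 input tags for cocaine and saline. Depth per sample was not used here, since each list pools its samples. With 1 list per treatment there is no replicate error, no library could be left out and no difference was tested against the spread between animals. Fisher's exact test and an exact sign test compare peaks and regions of the pooled lists only.

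From the deposited values, the local background of each peak was recovered from pileup and fold and divided by the genome-wide background, 1.17 fragments for cocaine and 0.986 for saline. A high-background peak has 10 times the genome-wide level or more, and an ordinary background is under 3 times. Both limits were chosen after seeing the data. The input background before scaling was obtained by undoing the depth scaling of 0.429 for cocaine and 0.376 for saline. Overlap meant at least 1 bp, and chance was set by 1000 seeded random placements of the saline peaks on their own chromosomes with their own lengths. Chromosome lengths were taken as the last peak end on each. Shares carry Wilson 95% intervals, which cover counting error only. Clusters joined peaks of a list less than 10 kb apart, and 100 random placements gave the chance of a neighbour within 1 kb. Thinning drew each pileup binomially at the depth ratio of the pools, in 20 draws, and kept the background in proportion. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used. The overlap and placement steps were tested on simulated data, where 1000 planted and 1000 random peaks against the 71325 placed cocaine peaks gave 50.45% overlapping with 0.768% by chance.

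The overlap test, its placements and the counting of peaks were fixed before the data were examined, and so were gene lists, promoter windows and motifs. Neither list names genes, and the gene table at hand is of the assembly GRCr8 while the peaks are on rn6. Coordinates were not converted, so promoter shares, genes with peaks, gene list percentiles and motif shares were not analysed here. The rule for named genes was kept for regions in their place. It takes the 10 peaks of highest fold in each list, the 10 shared peaks of highest cocaine fold, the 10 saline peaks of highest fold without a cocaine peak, and, in place of the genes with most peaks, the 10 clusters with most peaks. Ties went by position, and only placed chromosomes were named. Clusters at deep input, groups of low-background saline peaks and sites whose input differs between treatments were chosen after their values were seen. Alternatives tried were reciprocal overlap of 50%, edges within 1 kb, merging of peaks closer than 500 bp, the upper part of each list by fold, equal list lengths, equal −log10 p limits, placed chromosomes only, and each background class apart.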

Results

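INO80 is the catalytic ATPase of a chromatin remodelling complex that repositions nucleosomes and acts in transcription, replication and DNA repair. Its binding was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in the nucleus accumbens, a ventral striatal region of the brain's reward circuit, of rats given cocaine or saline. The labels place tissue collection 30 days after extended access to self-administered cocaine, and the saline samples carry the same protocol text. The series title makes craving in late withdrawal its subject, and the comparison asks where INO80 occupied the genome in each treatment at that time. The 24 libraries form 4 groups of 6, namely INO80 ChIP and sonicated input DNA from each treatment. Each group holds 3 numbered samples with 2 runs apiece, and whether a numbered sample is 1 animal is not given in the sources used here. The authors called peaks once per treatment, on the 3 ChIP samples together against the 3 inputs together. There is therefore 1 peak list per treatment and no replicate error. All values describe these 2 lists, and no difference between treatments was tested against the spread between animals. After filtering, 43489910 cocaine and 37905014 saline ChIP tags entered peak calling, a ratio of 1.15. The inputs held 101490635 and 100697179 tags, a ratio of 1.01. Depth is known for the pools and not for single samples.

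The cocaine list held many more INO80 peaks than the saline list and covered far more of the genome. It contained 71723 peaks over 9.74 Mb, against 2352 peaks over 0.311 Mb in the saline list, which is 30.5 times as many peaks and 31.3 times the covered length. Peaks were narrow in both lists, with a median length of 103 bp in the cocaine list and 91 bp in the saline list. The shortest peaks, 54 and 52 bp, were as long as the caller's fragment length, which was close to the 51 bp tag size. Width and number of peaks may depend in part on that setting and do not measure how INO80 binds. Joining peaks closer than 500 bp left 48552 cocaine and 1374 saline peaks. The lists also differed in the kind of site they held. The median pileup at the summit, which counts overlapping ChIP fragments, was 19 in the cocaine list and 58 in the saline list. The median fold enrichment over local input was 7.74 among cocaine peaks and 3.07 among saline peaks. The fold is a value of the authors' peak caller, scaled within each pool and used here to describe and rank the peaks of a list. Folds and pileups of both lists given side by side are each list's own values and not a measure of change. Placed chromosomes carried 71325 cocaine and 2300 saline peaks, and unplaced scaffolds carried 397 and 51. Thinning the cocaine pileups to the saline ChIP depth left at least 68862 peaks past the smallest −log10 p of the saline list, 4.94, in each of 20 draws.

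The local input background separated the lists. Most cocaine peaks stood on genomic sequence with ordinary input coverage, and most saline peaks stood where the input itself was deep. The median local background was 1.09 times the genome-wide level at cocaine peaks and 19.9 times that level at saline peaks. Peaks at 10 times the genome-wide background or more are called high-background peaks from here on, and the others low-background peaks. High-background peaks made up 2527 of the 71723 cocaine peaks (3.52%, Wilson 95% interval 3.39 to 3.66) and 1900 of the 2352 saline peaks (80.8%, 79.1 to 82.3). Intervals of shares cover counting error only, and neighbouring peaks are not independent. Numbers of high-background peaks were close, with 1.33 times as many in the cocaine list. Low-background peaks numbered 69196 in the cocaine list and 452 in the saline list, a ratio of 153. This ratio depended on where the limit was set and was 58.9 with a limit of 20 times background.

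**Figure D1:**
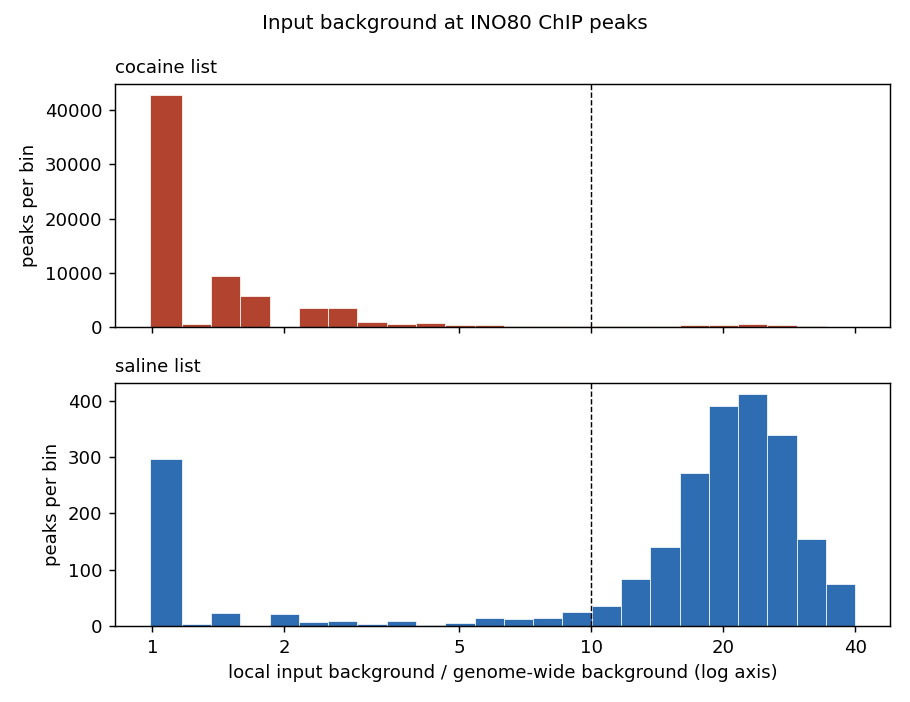
Number of INO80 peaks per bin (vertical axis) by local input background divided by the genome-wide background (horizontal log axis), for the cocaine list (upper panel) and the saline list (lower panel), each on its own scale. The dashed line marks 10 times the genome-wide background, with 69196 cocaine and 452 saline peaks to its left and 2527 and 1900 at or beyond it.

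Saline peaks were largely a subset of the cocaine sites, and the cocaine sites were largely absent from the saline list. A cocaine peak overlapped 1874 of the 2352 saline peaks by at least 1 bp (79.7%, 78.0 to 81.3). On placed chromosomes the share was 79.7%, against a mean of 0.728% and a highest value of 1.35% over 1000 random placements of the same peaks on their own chromosomes. Shifting all peaks of a chromosome together, which keeps their clustering, gave a highest value of 3.52%, and 14.9% for high-background saline peaks alone. Neither way of placing peaks matched the depth of the input. For high-background peaks the comparison therefore cannot separate shared binding from deep input shared by both lists. Low-background saline peaks on placed chromosomes, taken alone, had a share of 75.5% against at most 2.27% over random placements. Some low-background saline peaks met cocaine peaks of deep input, so this share is not free of it either. Of the 301 saline peaks under 3 times the genome-wide background that overlapped a cocaine peak, 44 overlapped a high-background one. Overlap was frequent for low-background saline peaks (341 of 452, 75.4%, 71.3 to 79.2) and for high-background saline peaks (1533 of 1900, 80.7%, 78.8 to 82.4). In the other direction 1802 of the 71723 cocaine peaks overlapped a saline peak (2.51%, 2.40 to 2.63). The high-background class supplied 1549 of these, out of 2527 (61.3%, 59.4 to 63.2). Of the 69196 low-background cocaine peaks, 253 overlapped a saline peak (0.366%, 0.323 to 0.413). With the cocaine list reduced to as many top-fold peaks as the saline list has, which leaves 0 high-background cocaine peaks, the saline share fell to 0.510%. Overlap of low-background saline peaks fell as well, from 341 to 12. A shorter cocaine list lowers overlap by its length alone, so this drop is no separate result.

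Low-background cocaine peaks were gathered in stretches rather than scattered. On placed chromosomes, 60.6% of them had another within 1 kb, against a mean of 6.08% for random placements. Part of this contrast may come from 1 enriched region being called as several short peaks. Joining peaks closer than 500 bp reduced the whole cocaine list from 71723 to 48552, and the neighbour comparison was not run on joined peaks. Joining peaks less than 10 kb apart gave 16683 clusters, of which 1846 held 10 peaks or more. These 1846 clusters contained 32270 peaks, 46.9% of the class, had a median span of 24.96 kb and together spanned 50.5 Mb. A saline peak lay in 76 of them (4.12%, 3.30 to 5.12). Of the 440 low-background saline peaks on placed chromosomes, 90 lay inside these clusters (20.5%, 16.9 to 24.5). With 0.158 such peaks per Mb genome-wide, an even spread would put far fewer than 90 into 50.5 Mb. The low share of clusters with a saline peak therefore does not show that saline peaks avoided them.

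The 10 largest low-background cocaine clusters had between 61 and 76 peaks each and at most 1 saline peak. At the genome-wide density of 0.828 saline peaks per Mb, most spans of this size would hold none. Counts of 0 or 1 therefore do not show a lack of saline peaks there. The largest, on chromosome 1 (82139813 to 82230846, rn6), had 76 peaks over 91.0 kb with a median fold of 8.75 and contained 0 saline peaks. Clusters of 70 peaks each lay on chromosome 1 (100837306 to 100914120, 1 saline peak), chromosome 11 (83881016 to 83949725, 0 saline peaks) and chromosome 7 (70846370 to 70901240, 0 saline peaks). The cluster on chromosome 6 (134958986 to 135022585) had 68 peaks and a median fold of 11.6. Chromosome X had a cluster of 67 peaks (21518227 to 21603307) with a median fold of 10.1. Clusters of 66 peaks lay on chromosome 3 (8547349 to 8615193) and chromosome 5 (157874699 to 157955923). The remaining clusters were on chromosome 20 (3290733 to 3381639, 63 peaks) and chromosome 12 (40702139 to 40799316, 61 peaks). Genes and gene parts at these coordinates were not analysed here.

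Chromosomes differed in their density of low-background cocaine peaks. The genome-wide density was 24.8 peaks per Mb. Chromosome 10 had 54.0 peaks per Mb and chromosome 12 had 44.9, followed by chromosome 19 with 32.1 and chromosome 3 with 31.2. Lower densities were found on chromosome 2 (15.7), chromosome X (17.5) and chromosome Y (6.92, from 22 peaks). In the saline list chromosome 10 also had the highest low-background density, 0.409 peaks per Mb from 46 peaks, against 0.158 genome-wide. High-background peaks followed another pattern, with chromosome 1 holding 41.1% of them in the saline list and 37.0% in the cocaine list. Chromosome 10, the densest in low-background peaks, held 0.158% and 0.514% of the high-background peaks.

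**Figure D2:**
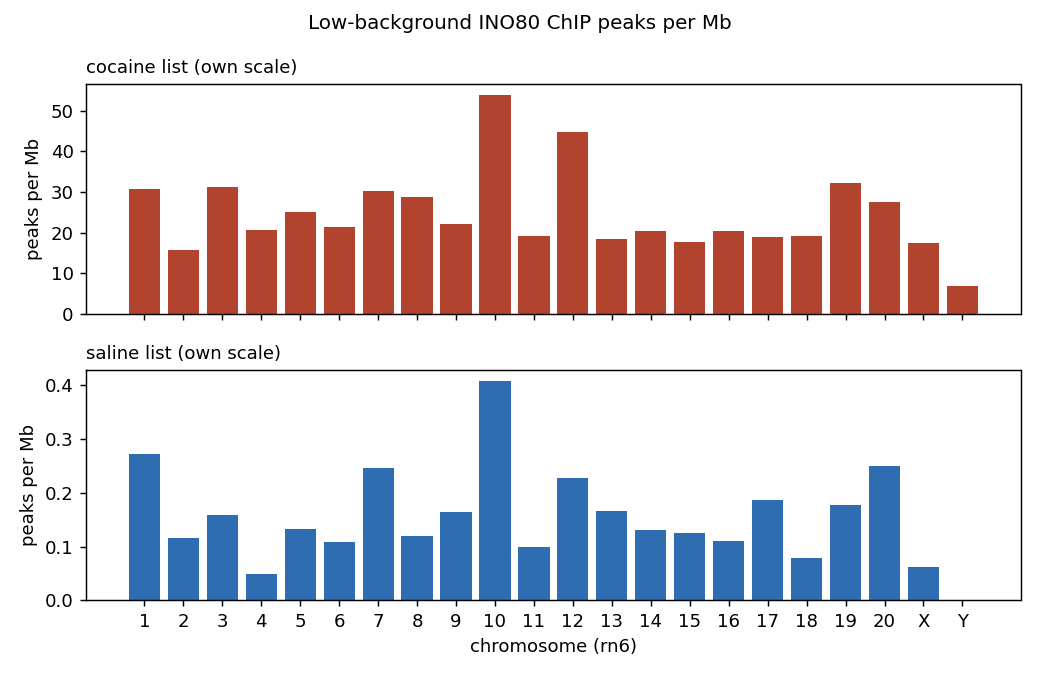
Low-background INO80 peaks per Mb (vertical axis, linear, from 0) on each rat chromosome (horizontal axis) in the cocaine list (upper panel) and the saline list (lower panel), each on its own scale. Chromosome 10 is highest in both, at 54.0 and 0.409 peaks per Mb.

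On placed chromosomes, the individual sites with the highest fold in the cocaine list were mostly without a saline counterpart. The same held for low-background cocaine peaks as a class, of which 0.366% overlapped a saline peak. The first was on chromosome 12 (11244014 to 11244130), with a pileup of 67 and a fold of 31.3, and it had no saline peak. Of the 10 highest, 1 overlapped a saline peak, at chromosome 1 (265469241 to 265469616). That site had a pileup of 64 and a fold of 29.9 in the cocaine list, and a pileup of 19 and a fold of 10.1 in the saline list. Other members were chromosome 3 (175551822 to 175552084, fold 29.5), chromosome 14 (86237375 to 86237476, fold 29.0) and a pair of neighbouring peaks on chromosome X. The pair lay at 156925600 to 156925780, with a fold of 28.9, and at 156924568 to 156924752, with a fold of 28.0. The remaining 4 sites, on chromosomes 10, 4, 15 and 2, had folds from 28.0 to 28.6. Unplaced scaffolds held still higher folds that were shared between the lists. They carried 4 of the 5 highest peaks of the whole cocaine list and all 5 of the saline list, and each of those 5 saline peaks overlapped a cocaine peak. The highest saline fold, 38.8, lay at the peak with the highest cocaine fold, 48.8.

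All 10 saline peaks of highest fold on placed chromosomes overlapped a cocaine peak. The first, on chromosome 1 (78354006 to 78354324), had a pileup of 25 and a fold of 13.1, with a pileup of 31 and a fold of 14.7 at the cocaine peak there. The site on chromosome 3 (161376486 to 161376732) had pileups of 23 in saline and 39 in cocaine. Chromosome 8 (23014658 to 23014955) had pileups of 29 and 35, and chromosome 11 (70966972 to 70967300) had 22 and 34. Pileups were not scaled to depth, and the cocaine ChIP pool was 1.15 times as deep. At 2 of these 10 sites the cocaine input was deep although the saline input was not. On chromosome 20 (29848514 to 29848572) the saline pileup was 21 and the cocaine pileup 88, with a cocaine fold of 6.85. On chromosome 10 (85073944 to 85074201) the pileups were 30 and 97, with a cocaine fold of 4.06.

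Among sites present in both lists, ranked by cocaine fold, the chromosome 1 site at 265469241 came first, followed by chromosome 1 at 60717171 to 60717513. The latter had a pileup of 51 and a fold of 23.9 in the cocaine list and 13 and 7.05 in the saline list. Next were chromosome 18 (37041552 to 37041617, folds of 18.9 and 8.67), chromosome 3 (161376462 to 161376913, 18.4 and 12.1) and chromosome 7 (2458238 to 2458538, 17.9 and 7.55). Saline peaks with no cocaine peak were absent from the 10 highest folds of the saline list. The first of them, on chromosome 3 (116097646 to 116097697), was 52 bp long with a pileup of 16 and a fold of 8.56. The others of highest fold had folds from 6.14 to 8.06, among them chromosome 3 (119802511 to 119802577) and chromosome 9 (65054042 to 65054127).

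Crowded stretches of deep input recurred in both lists, and their peaks are counted here at any background. The most crowded was on chromosome 14 (46580199 to 46687918), with 91 cocaine and 83 saline peaks and a median background of 20.8 times the genome-wide level in the cocaine list. Chromosome 1 held the next 3, at 180874989 to 180974482 (81 cocaine and 76 saline peaks), 55699127 to 55747292 (79 and 64) and 11903570 to 11975463 (76 and 72). Median folds in these 4 stretches lay between 2.10 and 3.10 in the cocaine list. Mitochondrial DNA was covered by 1 peak in each list (20 to 16295 and 20 to 16294), with folds of 2.32 and 2.66. Its pileups of 108 and 104 were the highest that the caller can give when 1 tag per position and strand is kept. The unscaled input background there, 107 and 102 fragments, lay near the same ceiling. The folds accordingly lay near the input-to-ChIP depth ratios of 2.33 and 2.66 and are no measure of INO80 binding there.

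**Figure D3:**
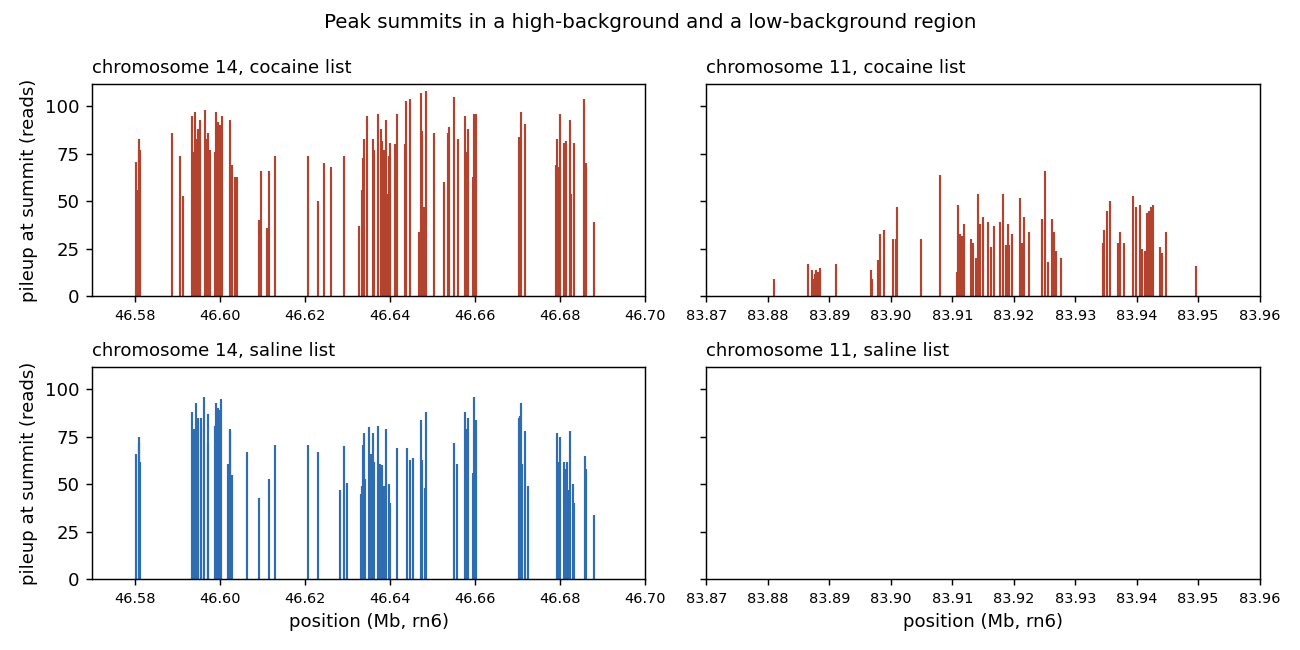
Pileup at each peak summit (vertical axis, ChIP reads) by position (horizontal axis, Mb, rn6) for the cocaine list (upper panels) and the saline list (lower panels). The chromosome 14 stretch on the left holds 91 cocaine and 83 saline peaks, and the chromosome 11 cluster on the right holds 70 cocaine and 0 saline peaks.

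Fold in the cocaine list did not order which low-background peaks had a saline counterpart. Over 10 equal groups by fold, the share with a saline peak ran from 0.231% to 0.535% without a steady rise. The group of lowest fold had 0.332% (0.222 to 0.498) and the group of highest fold had 0.303% (0.199 to 0.464). Above the median fold 128 of 34598 peaks overlapped a saline peak, and below it 125 of 34598 did, a ratio of 1.02 (95% interval 0.801 to 1.31). Fisher's exact test, two-sided and over peaks of these lists rather than animals, gave p = 0.90.

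**Figure D4:**
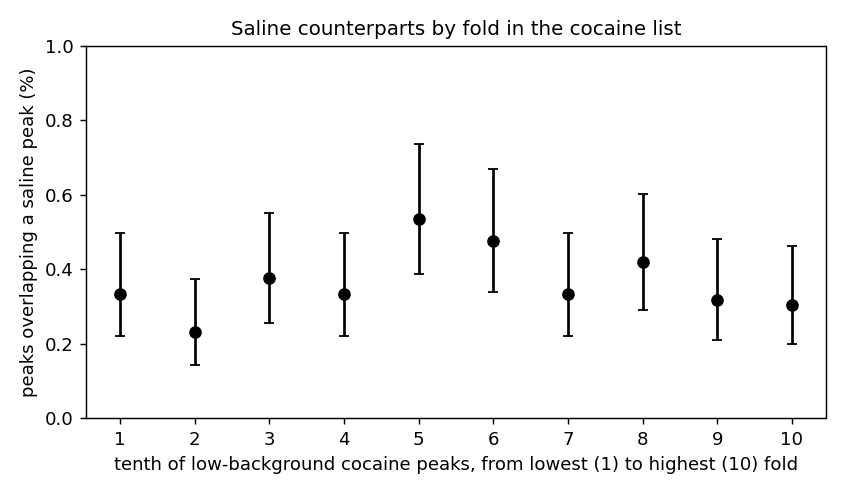
Percent of low-background cocaine peaks that overlap a saline peak (vertical axis) in 10 equal groups of peaks from lowest to highest fold in the cocaine list (horizontal axis). Points are shares and bars are Wilson 95% intervals, and all shares lie between 0.231% and 0.535%.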

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

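The tests in this part were all chosen after the result was seen. The input libraries served only as background in the report, and at some sites they carried a signal in the cocaine samples well above its level in the saline controls. Of the 364 saline peaks with ordinary input background (under 3 times the genome-wide level), 301 overlapped a cocaine peak. Among those 301, 44 overlapped a cocaine peak with at least 10 times the genome-wide level. These 44 saline peaks met 42 cocaine peaks on 16 chromosomes. The median input background there, before scaling to ChIP depth, was 42.5 fragments in the cocaine pool and 4.63 in the saline pool, although the input pools were nearly equal in depth (ratio 1.01). The limits that define the sites fix part of this gap. The ChIP pileup had medians of 101.5 in cocaine and 17 in saline, a gap also set in part by those limits, since a peak called on a deep input needs a high pileup. Sites with the deepest cocaine input lay on chromosome 2 (199203013 to 199203329, 79.0 against 6.55 fragments) and chromosome 7 (140615273 to 140615529, 73.0 against 7.80). Sites on chromosome 16 (69940656 to 69940723) and chromosome 1 (69266350 to 69266417) had the same length of 68 bp, the same saline pileup of 25 and cocaine pileups of 106 and 107.

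Chance differences of input reads between the pools should go both ways. The reverse difference, a deep saline input at a cocaine peak of ordinary background, could be seen only where the saline list also held a peak. It was found at 0 of the 225 cocaine peaks of ordinary background that overlapped a saline peak. The 44 saline peaks in the direction seen fall into 33 regions more than 10 kb apart, all with the deep input in cocaine (exact sign test over regions, two-sided, p = 2.3e-10). The p-value takes regions as independent, which repeated values put in doubt. Sites on chromosomes 10 (40381730) and 5 (138336325) shared a saline pileup of 24 and a cocaine input of 50 fragments. Sites on chromosomes 18 (24781868) and 10 (109519968) shared pileups of 14 in saline and 104 in cocaine. The number of independent regions is unknown, so the p-value does not measure strength. The direction, 44 against 0, argues against chance in the input reads of these pools by an unknown margin. It says nothing of the spread between animals. Additional copies of these sequences in the DNA of one or more cocaine samples, for instance from an added or amplified DNA, may give such a signal, and the median of 42.5 fragments is what that explanation has to account for. It cannot be told apart from a difference shared by all cocaine samples, a treatment effect included, because the lists pool the samples and the rn6 sequence of the sites was not used here.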

How the results depend on the processing

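Alternatives by background class were chosen after seeing the data, and the others before the data were examined. Of 28 alternatives to 6 results, 10 left the value within its limits (1.5 times for a count, the 95% interval for a share) and 18 moved it. The cocaine list stayed the longer one in each count, by 30.1 to 35.3 times for the whole lists and by 58.9 and 177 times for low-background peaks with limits of 20 and 5 times background. Counts moved by construction where peaks were dropped or joined. The upper part by fold held 35863 cocaine and 1177 saline peaks, merging left 1374 saline peaks, and low-background saline peaks numbered 452, or 1195 with a limit of 20 times. The share of saline peaks overlapping a cocaine peak was 60.5% with reciprocal overlap, 89.6% with edges within 1 kb, 76.2% after merging and 75.4% for low-background peaks. The share of cocaine peaks overlapping a saline peak was 1.98%, 3.47%, 2.09% and 0.366% under the same settings, and 61.3% for high-background peaks. With the cocaine list reduced to the length of the saline list both shares were 0.510%, and with the upper part of each list by fold they were 12.6% and 0.374%. Those settings rank by fold and thereby keep 0 and 1 of the 2527 high-background cocaine peaks, while the upper part of the saline list keeps 737 high-background peaks. Overlap of the 452 low-background saline peaks also fell, to 12 with the reduced cocaine list, where the shorter list lowers overlap by its length alone. No paired analysis was possible because each list pools all samples of a treatment, and for the same reason no sample could be left out. The alternatives for promoters, genes and gene lists were not run, since no rn6 annotation was used here. Shifting all peaks of a chromosome together in place of independent placement, also chosen after seeing the data, gave overlaps of at most 3.52% over 1000 shifts for all saline peaks, 2.05% for low-background and 14.9% for high-background ones. The ChIP pools differed in depth by a ratio of 1.15, and the spread between samples is unknown.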

Other observations

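Low-background cocaine peaks lay in most megabase windows but were unevenly spread over them. Of 2790 windows of 1 Mb, 283 held no such peak, the median window held 12, and the richest 10% of windows held 45.0% of the peaks. The richest was on chromosome 7 (11000001 to 12000000), with 286 low-background cocaine peaks and 1 low-background saline peak, the classes counted in all these windows, and the next megabase of that chromosome (12000001 to 13000000) had 258 and 3. Chromosome 10 (56000001 to 57000000) had 270 and 1, and chromosome 7 (70000001 to 71000000) had 264 and 0. Chromosome X (156000001 to 157000000) had 254 and 5. That window contains the pair of chromosome X peaks named among the highest folds.

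Most low-background saline peaks stood alone, and a minority formed small groups. Of 382 clusters at 10 kb, 348 held a single peak. Of the 440 peaks on placed chromosomes, 17.7% had another within 1 kb, against a mean of 0.05% for random placements. The largest groups held 5 peaks, on chromosome 2 (199199887 to 199203496) and chromosome 7 (140719854 to 140723472), and all 5 peaks of each overlapped a cocaine peak. In these groups 2 and 3 of the peaks met a deep cocaine input, as defined for the sites whose input differed between the pools. Groups of 4 numbered 5, and 4 of them also held such a peak, on chromosome 1 (69266350 to 69267212), chromosome 16 (69940656 to 69941518), chromosome 17 (31495790 to 31498313) and chromosome 5 (161924563 to 161925564). The group on chromosome X (156811647 to 156812803) held 0.

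The tests in the rest of this part were chosen after the result was seen. The excess of cocaine over saline peaks was weighed against sequencing depth first. Thinned to the saline ChIP depth, at least 68862 cocaine peaks stayed past the saline list's own smallest −log10 p, so depth does not account for the excess. A saline profile of the same shape but uniformly weaker would keep the strongest cocaine sites, yet the share with a saline counterpart was 1.02 times as high above the median fold as below it (95% interval up to 1.31), which argues against such a profile as the source of the shared peaks. Low-background saline peaks lay in the large cocaine clusters (90 of 440) more often than an even spread would give. Such a profile could give that too. A saline signal so weak that hardly any site passes the caller's limit stays open. So do a failed or weak immunoprecipitation in one treatment's libraries or one outlying library, which may produce the same excess of peaks and cannot be told apart from the treatment with 1 pooled list per treatment.

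The deep-input position of most saline peaks was weighed likewise. Of the high-background saline peaks, 80.7% overlapped a cocaine peak, so most of these sites were not particular to the saline list. The overlap cannot decide on binding present in saline animals only, because a deep input shared by both lists could give it too. Duplicate removal may level ChIP and the deeper input where positions are full of reads, and the caller then scales the input down. The ChIP pileup at these peaks was a median of 1.10 times the unscaled input background, where 0.376 would stand without enrichment or levelling, and their median fold of 2.84 lay near the input-to-ChIP depth ratio of 2.66. At the mitochondrial peak levelling is plain, since ChIP and input both lay near the ceiling set by duplicate removal. For the other high-background peaks levelling and enrichment cannot be told apart here, because the caller's limit keeps sites with a lower ratio out of the list.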
